A study of Mus musculus with 8 samples.

How the data were processed

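Bulk RNA sequencing was done on total RNA from primary mouse VSMCs, extracted with TRIzol and prepared with a NEBNext Ultra RNA kit, per the labels. Of 8 libraries, 4 came from control cells and 4 from cells with Sox6 knockdown, per the labels. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The values used were counts of reads per gene as deposited, whole numbers that the authors did not normalize. The submitters' processing notes name the genome build mm10 and DESeq2. The aligner, the counting tool and its strand setting are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand can therefore not be told apart, and counts of near-identical genes depend on an unknown rule for reads that fit several places. Between 72% and 74.2% of the counts from 1 to 40 were even numbers in each library, as when the 2 reads of a pair are counted singly. Counts halved were therefore tried as an alternative.

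Gene symbols, positions and exon overlaps were taken from GENCODE M21, an annotation of the same build, which gave a symbol for 30008 of 30660 identifiers and none for 652. Total counts per library ran from 37604102 to 49393224, so that 3 counts, the floor used for a count of 0, correspond to 0.0607 to 0.0798 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Within groups, pairs of libraries differed by 6.15 to 17.6 chi-square units per degree of freedom (3.07 to 8.82 on halved counts) over genes with a summed count of at least 20, so no pair differed by as little as sampling noise.

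The tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 16150, and libraries were scaled by TMM. Knockdown was compared with control by the quasi-likelihood test (glmQLFit and glmQLFTest) over all 8 libraries with no covariate, and Benjamini-Hochberg adjusted p-values under 0.05 were called. CPM were computed from TMM-scaled library sizes and are given as mean ± SD (n = 4 per group), except where total scaling is named. Log2 fold changes are knockdown minus control. The common biological coefficient of variation was 0.0777, and its median was 0.0502 over the 2291 genes above 100 CPM. Sox6 was tested by an exact two-sided permutation test over the 70 assignments, and its ratio has an exact 95% interval from the binomial split of its counts.

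The design, alternatives and 38 gene lists were fixed before the data were examined. Lists with at least 5 tested members, 36 in number, were tested with camera (preset correlation 0.01, and estimated) and fry from limma 3.58.1. The genes named in the text follow a rule fixed at the same time. It takes Sox6 with 20 genes of the SoxD family, smooth muscle, autophagy and angiotensin signalling, and the 12 largest changes each way with an average log2 CPM of at least 1 and groups that do not overlap. It adds the 10 smallest p-values, up to 4 members of each list with the smallest p past the threshold (2 members where none passed), and genes with a library far from its group. Values of 3 genes taken by this rule are not reported here. Genes outside it are said to be singled out after their values were seen.

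The test was first run on simulated data for the knockdown and control libraries, with 200 of 15888 genes changed. Of 50 genes each, 16 were recovered at 1.2 fold, 36 at 1.5 fold, 43 at 2 fold and 46 at 4 fold, and 12 of 153 calls were false. Camera called 5 of 5 simulated sets that were moved and 0 of 30 that were not. The simulated genes varied independently, whereas the estimated correlation in the real G2 and mitosis list was 0.856. This check therefore does not cover false calls for lists whose genes move together. The simulation also changed far fewer genes than the 8311 called in the real data. It does not show how scaling and camera behave where many genes change. Alternatives were DESeq2 size factors, upper quartile and total count scaling, no filter, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01, glmTreat against 1.5 fold, and leaving out libraries singly or by number. Halved counts and offsets for GC content and transcript length were added after the data were seen.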

Results

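RNA from primary mouse vascular smooth muscle cells (VSMCs), the muscle cells of the vessel wall, was sequenced in 8 libraries. Control cells gave 4 libraries and cells with knockdown of Sox6 gave 4. Sox6 encodes a transcription factor of the SoxD family, and the series title links it to VSMC phenotype, autophagy and blood pressure. The gene table held 30660 gene identifiers, of which 1049 had no counts in these libraries. Total counts ran from 41672921 to 48039788 in the 4 controls and from 37604102 to 49393224 in the 4 knockdowns, a difference of means within the spread between libraries (exact permutation test, two-sided p = 0.857). Correlations of log2 CPM ran from 0.991 to 0.992 within groups and from 0.972 to 0.975 between groups. The first principal component separated the groups and carried 61.4% of the variance.

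Sox6 itself (ENSMUSG00000051910, mm10 chromosome 7, 115470872 to 116038796) was close to the detection limit in both groups. The control libraries held 6, 10, 6 and 4 counts, and the knockdown libraries held 2, 4, 0 and 0. Mean abundance was 0.144 ± 0.0527 CPM in controls and 0.0318 ± 0.0394 CPM in knockdowns (SD, n = 4 each, scaled to total counts). The ratio of knockdown to control was 0.221, with a 95% exact interval of 0.0788 to 0.582 from 32 counts, or 0.0428 to 0.852 if each read pair was counted as 2. In CPM all 4 knockdown libraries were below the lowest control, and an exact permutation test gave a two-sided p = 0.0286, the smallest that 4 against 4 can give. The edgeR filter on low counts left Sox6 out. Without that filter its log2 fold change was -2.13 with an edgeR adjusted p = 0.0774, so the genome-wide threshold was not reached. The zero counts in knockdown replicates 3 and 4 allow up to 0.0798 and 0.0641 CPM (3 counts each), which covers counting error only. The other SoxD members were more abundant or similarly rare. Sox5 fell from 27.1 ± 2.43 to 19.9 ± 0.521 CPM (log2 fold change -0.45 ± 0.07 SE, edgeR adjusted p = 6.63e-05). Sox13 was at 0.528 ± 0.232 and 0.214 ± 0.1 CPM (log2 fold change -1.31, adjusted p = 0.0173). The Sox13 call was lost without control replicate 4 (-1.05, adjusted p = 0.0718), knockdown replicate 1 (-1.15, adjusted p = 0.0516) or knockdown replicate 2 (-1.18, adjusted p = 0.0517), and without replicate 2 (-1.07, adjusted p = 0.104) or replicate 4 of both groups (-1.04, adjusted p = 0.109).

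Knockdown cells differed from controls in 51.5% of the tested genes, mostly by small amounts. Transcripts of the connective tissue growth factor Ccn2, the slow myosin Myh7 and the cytokine Il6 were among the 12 largest decreases. Every tested gene of 2 cell cycle lists fell, and every tested gene of cholesterol synthesis rose. Targets of the co-activator YAP and of TGF-beta mostly fell, the only lists to pass with an estimated correlation. Of 27 matrix genes 19 fell, elastin among them. Of 16150 tested genes, 8311 passed an edgeR adjusted p of 0.05, 4105 higher and 4206 lower in the knockdown. Only 1453 of these changed by over 2 fold, 657 upward and 796 downward, while 5426 changed by under 1.5 fold. With the filter of 1 CPM in at least 4 libraries, which tests fewer genes, 798 changed by over 2 fold. In 7572 genes (46.9%) the 4 knockdown values lay outside the range of the 4 controls on 1 side, where chance gives 2.86%. Scaling by total counts instead of TMM raised the median log2 fold change of all tested genes from 0.02 to 0.12, and the split became 5926 higher and 3045 lower. Directions below hold relative to that shift, and no gene called under both scalings changed sign.

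**Figure D1:**
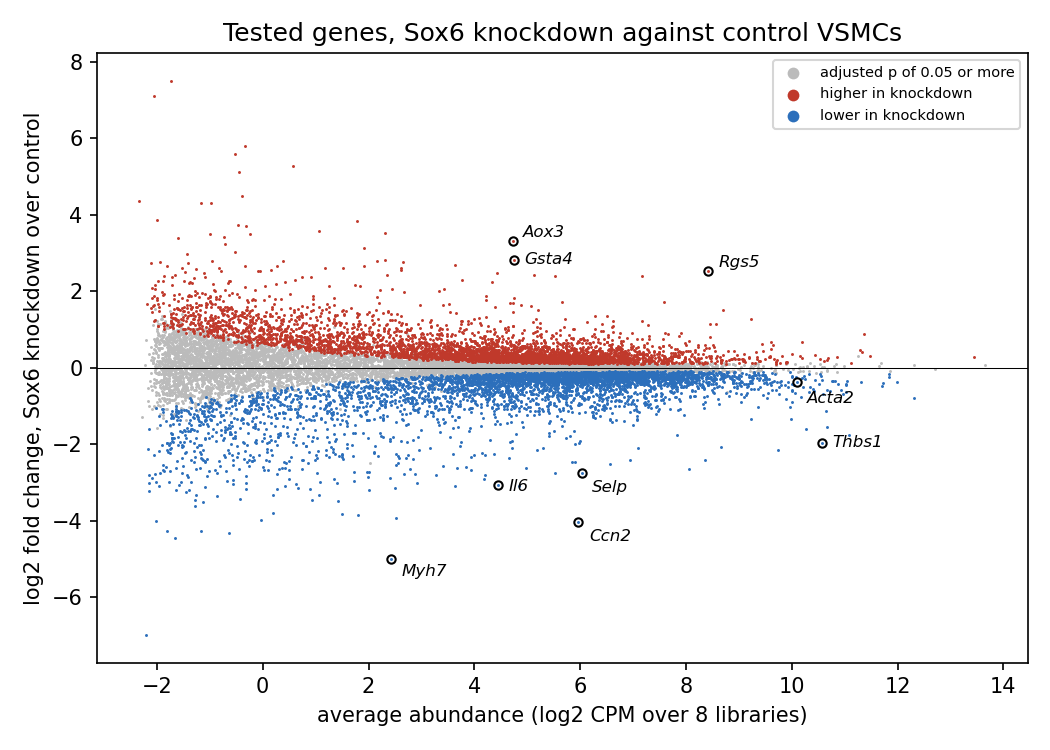
Log2 fold change of each of the 16150 tested genes (knockdown over control) against its average abundance in log2 CPM over 8 libraries, with 4105 genes called higher in red, 4206 called lower in blue and the rest in grey. Labelled genes include Ccn2 at -4.03 and Rgs5 at 2.52.

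Among the 12 largest decreases, Myh7 fell from 10.4 ± 1.6 to 0.321 ± 0.27 CPM (log2 fold change -5.0 ± 0.31 SE, edgeR adjusted p = 1e-08). Ccn2 fell from 118 ± 10.5 to 7.23 ± 1.2 CPM (-4.03 ± 0.10, adjusted p = 1.28e-12). Col28a1 (-3.92), Clip4 (-3.86), the imprinted non-coding RNA H19 (-3.83), Sorcs2 (-3.48), Col6a3 (-3.33), Moxd1 (-3.19), Sprr2a3 (-3.14), cardiac actin Actc1 (-3.11), Tnfsf18 (-3.08) and Il6 (-3.07) made up the rest. Sprr2a3 belongs to a family of near-identical genes, so its counts are uncertain. The 12 largest increases included Gng2 (3.57), Cyp3a13 (3.51), Aox3 (3.32), Lcp1 (3.12), the glutathione transferase Gsta4 (2.83), Syt1 (2.80), Klf12 (2.80), Ces1d (2.75), the lysosomal glycoprotein gene Gpnmb (2.70), Sytl2 (2.65) and Gbp8 (2.61). The smallest p-values were those of the adhesion receptor Selp, which fell from 114 ± 3.68 to 16.9 ± 0.969 CPM (-2.75, adjusted p = 8.49e-14), of the G protein regulator Rgs5, and of Timp3. Rgs5 rose from 102 ± 4.76 to 584 ± 28.3 CPM (2.52, adjusted p = 8.49e-14), and Timp3 fell from 654 ± 8.87 to 154 ± 5.98 CPM (-2.09). Aox3, Ankrd1, Il33, Ccn2, Ccn1, Thbs1 and Ltbp1 completed the 10 smallest p-values.

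Cell cycle genes were lower in the knockdown throughout. All 30 genes of G2 and mitosis fell (median log2 fold change -0.997), among them Cdk1 from 120 ± 6.54 to 58.3 ± 3.44 CPM (-1.04), Foxm1 (-1.18) and Aurka (-0.97). All 34 genes of DNA replication fell (median -0.94), among them Mcm5 (-1.39), Cdc45 (-1.21) and Tk1 (-1.16). The counts adjusted over the list alone were also 30 and 34. In the camera test the adjusted p-values were 1.15e-29 and 2.74e-25. They were adjusted p = 0.112 and adjusted p = 0.121 with an estimated correlation. Of 20 p53 target genes, 12 rose and 2 fell (12 and 3 adjusted over the list alone), with Trp53inp1 at 1.21, the BH3 protein gene Bbc3 at 0.88 and Sesn1 at 0.64. The p53 list had camera adjusted p = 0.000144, and adjusted p = 0.0564 with an estimated correlation. Of 28 apoptosis regulators, 11 rose and 6 fell, and the list was not past the threshold (camera adjusted p = 0.0874), though it passed under 3 of 25 alternatives, such as total count scaling (adjusted p = 0.0355). Bmf rose (1.59) and Bcl2l1 fell (-0.43). Of 22 immediate early genes, 14 fell and 2 rose, with Egr1 at -2.11, Fosl1 at -1.48 and Myc at -0.73 (camera adjusted p = 3.2e-06, and adjusted p = 0.112 with an estimated correlation). Exons of Fosl1 overlap those of another gene over 57.2% of their length.

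Genes of sterol synthesis and its regulation rose as a group. All 25 rose (25 adjusted over the list alone), with a median log2 fold change of 0.96, including Dhcr7 from 14.3 ± 2.19 to 44.8 ± 2.76 CPM (1.65), Mvd (1.63) and Lss (1.34). The camera adjusted p was 2.12e-23, and adjusted p = 0.112 with an estimated correlation. Of 27 glycolysis and hypoxia genes, 19 fell and 2 rose, with Hk2 at -0.95 and Pgk1 at -0.61 (camera adjusted p = 0.000144, and adjusted p = 0.351 with an estimated correlation). Of 40 oxidative phosphorylation genes, 7 rose and 8 fell (6 and 7 adjusted over the list alone). Ndufs3 was at 0.31 and Cycs at -0.40, and the list was not past the threshold (camera adjusted p = 0.901). Of 13 genes encoded by mitochondrial DNA, 2 rose and 1 fell (camera adjusted p = 0.682), with mt-Co1 at 0.27 and mt-Cytb at -0.24. Mitochondrial transcripts took 2.21 ± 0.0328% of counts in controls and 2.62 ± 0.145% in knockdowns (SD, n = 4 each, exact permutation p = 0.0286, 0.0667 after Benjamini-Hochberg adjustment over 7 library measures). Of 26 antioxidant genes, 12 rose and 9 fell, with Gclc at 0.89, Nqo1 at 1.14 and Slc7a11 at -0.75 (camera adjusted p = 0.00597, and adjusted p = 0.226 with an estimated correlation). The antioxidant call was also lost with limma-voom (adjusted p = 0.135, and 0.141 with sample weights). Of 40 cytosolic ribosomal protein genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone), with Rps19 at 0.60 and Rps24 at 0.26. A wider set, all protein-coding genes whose symbols start with Rpl or Rps and a digit, was used for the share of counts. That share was 4.23 ± 0.0738% in controls and 4.93 ± 0.139% in knockdowns (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.0667). The ribosomal list had camera adjusted p = 0.00365, adjusted p = 0.363 with an estimated correlation, and adjusted p = 0.0643 with offsets for GC content and length.

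YAP and TGF-beta targets fell, and these were the 2 lists whose camera calls held with an estimated correlation. Of 18 YAP targets, 14 fell and none rose (15 adjusted over the list alone), with a median log2 fold change of -0.61. Ankrd1 fell from 459 ± 19.9 to 73.3 ± 6.7 CPM (-2.65), Ccn1 from 102 ± 3.27 to 18.4 ± 1.97 CPM (-2.46) and Amotl2 from 190 ± 10.5 to 78.6 ± 0.858 CPM (-1.27). The camera adjusted p was 1.43e-28, and adjusted p = 0.000635 with an estimated correlation. Of 19 TGF-beta targets, 13 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.47. Ltbp1 fell from 353 ± 14.8 to 103 ± 6.47 CPM (-1.77), as did Id3 (-1.49). Its camera adjusted p was 2.64e-21, and adjusted p = 0.00264 with an estimated correlation. Ccn2 was in both lists. Of 27 matrix and crosslinking genes, 19 fell and 2 rose (19 and 3 adjusted over the list alone). Elastin (Eln) fell from 97.5 ± 1.89 to 17.8 ± 2.29 CPM (-2.46), fibulin 2 (Fbln2) from 2412 ± 129 to 826 ± 48.5 CPM (-1.55) and Fbln5 (-1.37). The matrix list had camera adjusted p = 7.53e-15, and adjusted p = 0.0572 with an estimated correlation. Fbn2, a fibrillin gene singled out after its values were seen, had 61 counts over the controls and 0 over the knockdowns. The 95% exact upper bound of its ratio was 0.0633, which was not widened for read pairs counted as 2. Of 19 collagen genes, 9 fell and 4 rose, with Col5a2 at -0.85, Col8a1 at -0.91 and Col14a1 at -0.94 (camera adjusted p = 0.00141, and adjusted p = 0.112 with an estimated correlation).

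Smooth muscle genes of both the contractile and the synthetic state were mostly lower in the knockdown. Of 26 contractile genes, 17 fell and 1 rose (the same counts adjusted over the list alone), with a median log2 fold change of -0.38. Smooth muscle actin Acta2 fell from 1240 ± 136 to 949 ± 102 CPM (-0.39, adjusted p = 0.00108), Cald1 from 651 ± 11.4 to 403 ± 21.3 CPM (-0.69), Tpm2 (-0.62), Vcl (-0.45) and Smtn (-0.38). Myocd, the co-activator of contractile genes, fell from 0.414 ± 0.0434 to 0.0668 ± 0.0465 CPM (-2.61), on 72 and 12 counts. Heart muscle cells also express Myocd, and its fall was close to that of the striated muscle genes below (median -2.59), so the source of this change is open. The only member that rose was Fbxo32 (0.95), a ubiquitin ligase gene known from muscle atrophy. Cnn1 (2.23 ± 0.487 and 1.92 ± 0.769 CPM, adjusted p = 0.473) and Myh11 (5.9 ± 0.987 and 7.28 ± 2.45 CPM, adjusted p = 0.213) did not pass. Leaving out replicate 4 of both groups turned Cnn1 from -0.23 to 0.10 and brought Myh11 past the threshold (0.53, adjusted p = 0.0406), as did leaving out the expression filter (0.30, adjusted p = 0.0284). Tagln had 20 counts over the controls and 38 over the knockdowns and was not tested, and 67.9% of its exon length overlapped other genes. The contractile list had camera adjusted p = 0.00262, and adjusted p = 0.114 with an estimated correlation. Of 25 genes of the synthetic state, 15 fell and 3 rose (the same counts adjusted over the list alone), with a median of -0.43. Thbs1 fell from 2410 ± 161 to 614 ± 30.2 CPM (-1.97), fibronectin (Fn1) from 3368 ± 168 to 986 ± 47.3 CPM (-1.77), Tnfrsf11b (-2.27), Tnc (-1.78), Vim (-0.47) and Klf4 (-0.25), while Pdgfra rose (1.02). Spp1 fell by 0.18 on the log2 scale (adjusted p = 0.016), a call lost with upper quartile scaling (adjusted p = 0.0559), with total count scaling (adjusted p = 0.276), and without replicate 1 (adjusted p = 0.077) or replicate 3 of both groups (adjusted p = 0.0627). The synthetic list had camera adjusted p = 2.66e-12, and adjusted p = 0.0572 with an estimated correlation.

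Of 29 genes of vasoactive receptors and their signalling, 14 fell and 4 rose, and the list was not past the threshold (camera adjusted p = 0.226), though it passed under 3 of 25 alternatives, such as limma-voom (adjusted p = 0.0192). The alpha-1B adrenoceptor Adra1b fell from 12.8 ± 1.02 to 5.67 ± 0.356 CPM (-1.17), the guanylate cyclase subunit Gucy1b1 fell (-0.89), and Rgs4 rose (1.85). The angiotensin receptor Agtr1a had 20 and 14 counts over the groups and was not tested, and Ren1 was not analysed here. Angiotensinogen (Agt), singled out after its values were seen, had 4 counts over the controls, all in replicate 1, and 69, 60, 43 and 56 counts in the knockdown libraries. The Agt ratio was 57.9, with a 95% exact interval of 22.3 to 214 that covers counting error only (edgeR adjusted p = 1.71e-06).

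Most lysosome and V-ATPase genes were higher in the knockdown by small amounts, while under 50% of the autophagy genes were. Of 40 core autophagy genes, 19 rose, 3 fell and 18 did not pass (19 and 3 adjusted over the list alone), with a median log2 fold change of 0.16. Map1lc3b, whose product coats autophagosomes, rose from 128 ± 8.2 to 180 ± 9.47 CPM (0.50 ± 0.05 SE, adjusted p = 2.08e-06). Tecpr1 (0.65), Atg7 (0.40), Atg13 (0.34) and Ulk1 (0.24) rose, and Wipi1 fell (-0.30). Becn1 was at 55.9 ± 2.9 and 56.1 ± 2.77 CPM (log2 fold change 0.0049, adjusted p = 0.942), a sign that turned with DESeq2 size factors (-0.00022). Atg5 was at 22.8 ± 2.62 and 25.4 ± 2.04 CPM (0.16, adjusted p = 0.129). Atg5 passed the threshold with total count scaling (0.26, adjusted p = 0.023), without control replicate 3 (0.22, adjusted p = 0.0341) and without knockdown replicate 1 (0.21, adjusted p = 0.0456). The core list had camera adjusted p = 0.0129, and adjusted p = 0.305 with an estimated correlation. Of 19 autophagy receptors and mitophagy genes, 8 rose and 2 fell (camera adjusted p = 0.133, and 0.0364 with total count scaling), including Sqstm1 from 903 ± 86.6 to 1151 ± 103 CPM (0.35), Calcoco1 (0.50) and Ncoa4 (0.29). Tax1bp1 fell by 0.19 on the log2 scale (adjusted p = 0.00229), a call lost with total count scaling (adjusted p = 0.129). Of 40 lysosome genes, 29 rose and 2 fell (30 and 2 adjusted over the list alone), with a median of 0.29. Cathepsin D (Ctsd) rose from 290 ± 15.8 to 435 ± 11.7 CPM (0.58), Ctsk (0.91), Ctsl (0.60), Mcoln1 (0.57) and Lamp1 (0.24). The camera adjusted p was 8.62e-06, and adjusted p = 0.305 with an estimated correlation. Of 16 genes of the V-ATPase, the proton pump that acidifies lysosomes, 13 rose and 1 fell, with a median of 0.40. Atp6ap2 rose (0.61), as did Atp6v1b2 (0.48), Atp6v1a (0.46) and Atp6v1g1 (0.45). That list had camera adjusted p = 4.83e-06, and adjusted p = 0.112 with an estimated correlation. Of 34 genes of mTOR, AMPK and FoxO signalling, 13 rose and 8 fell (14 and 8 adjusted over the list alone), with Ddit4 at 0.82, Sesn1 at 0.64 and Flcn at 0.47 (camera adjusted p = 0.143, and 0.0462 with total count scaling).

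**Figure D2:**
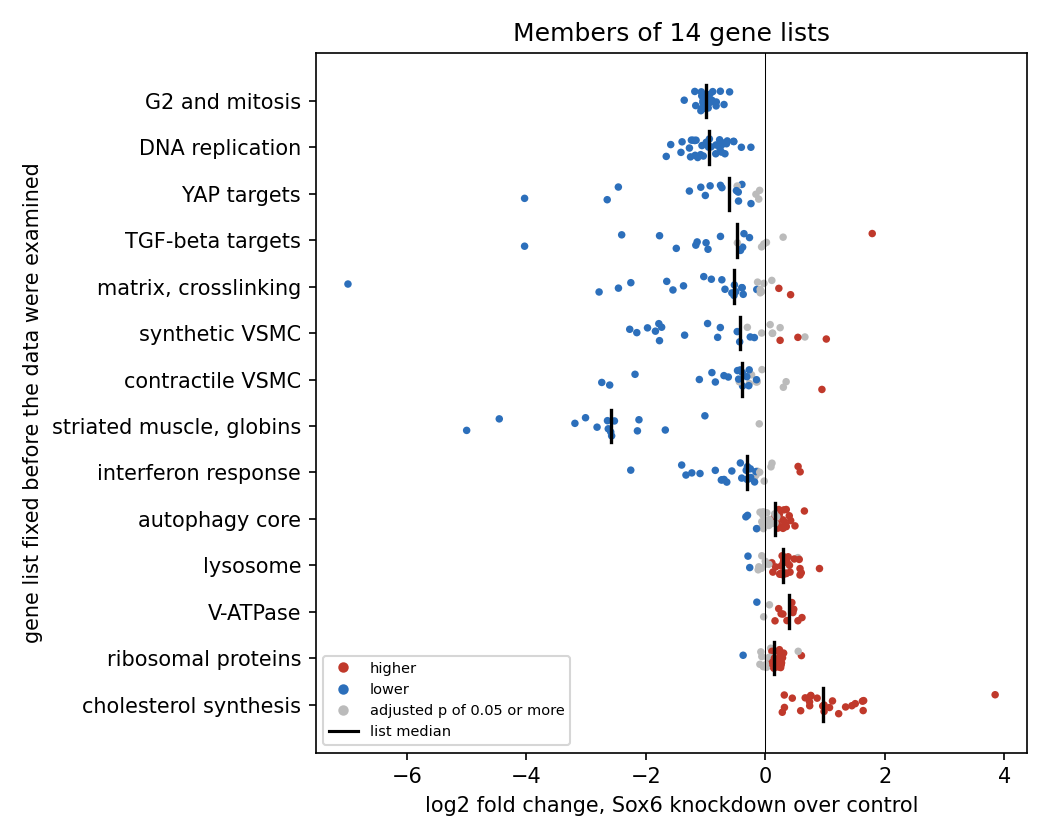
Log2 fold change (knockdown over control) of each tested member of 14 gene lists, 1 point per gene, red if higher, blue if lower and grey if not past the threshold, with list medians as black bars. The medians run from -2.59 for striated muscle genes and globins to 0.96 for cholesterol synthesis, and the point near -7 is Fbn2, fitted from 0 knockdown counts.

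Inflammatory and stress response genes were mostly lower. Of 26 NF-kB target and inflammatory genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone). Il6 fell from 39.0 ± 4.87 to 4.62 ± 0.759 CPM (-3.07), Il33 (-1.98), Lif (-1.51) and the chemokine Ccl2 from 2196 ± 288 to 996 ± 126 CPM (-1.14). The camera adjusted p was 1.87e-07, and adjusted p = 0.264 with an estimated correlation. Of 31 interferon response genes, 22 fell and 2 rose (23 and 2 adjusted over the list alone), with Cxcl10 at -2.25, Ifit2 at -1.09 and Ifit3 at -1.33. Ifit3 and its neighbour Ifit3b (-1.23) are near-identical copies whose counts are uncertain. The interferon list had camera adjusted p = 6.19e-07, and adjusted p = 0.305 with an estimated correlation. Of 21 unfolded protein response genes, 14 fell and 1 rose, with Hspa5 from 1068 ± 21.6 to 662 ± 27.6 CPM (-0.69), Calr (-0.57) and Pdia4 (-0.49). That list had camera adjusted p = 0.000422, and adjusted p = 0.112 with an estimated correlation. Of 25 integrated stress response genes, 13 fell and 5 rose (13 and 6 adjusted over the list alone), with Atf4 at -0.36 and Gdf15 at 0.78 (camera adjusted p = 0.393). Of 14 Sox and cartilage genes, 7 fell and 2 rose (7 and 4 adjusted over the list alone), with Bmp4 at -0.87, Sox12 at -0.38 and Sox4 at 0.71 (camera adjusted p = 0.388). Exons of Sox4 overlap those of another gene over 54.6% of their length.

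Markers of other cell types also differed between the groups. Of 15 striated muscle and globin genes of a fixed list, 14 fell and none rose, with a median log2 fold change of -2.59. Tnnt2 fell from 59.6 ± 5.24 to 13.5 ± 3.31 CPM (-2.14), Tnni1 (-3.01) and Tnnc1 (-1.67). The list had camera adjusted p = 1.31e-09, and adjusted p = 0.0564 with an estimated correlation. Atrial and adult cardiac myosin Myh6, singled out after its values were seen, had 8169, 5490, 6380 and 7770 counts in controls and 792, 551, 950 and 2864 in knockdowns. Adult haemoglobin transcripts summed to 7.51 ± 1.18 CPM in controls and 1.43 ± 0.964 CPM in knockdowns (exact permutation p = 0.0286, 0.0381 after adjustment over 8 marker groups). Of 14 endothelial genes, 9 fell and 3 rose (10 and 3 adjusted over the list alone), with Cdh5 at -2.43, Kdr at -2.41, Tie1 at -2.41 and Vwf at 1.51 (camera adjusted p = 0.133). Their summed CPM moved little, from 276 ± 17 in controls to 251 ± 11.3 in knockdowns (exact permutation p = 0.0857). The median abundance of these genes in controls was only 1.1 CPM. The sum therefore rests on the most abundant members and does not show that endothelial content was unchanged. Of 10 epithelial and mesothelial genes, 6 fell and none rose, with Upk3b from 41.5 ± 1.45 to 11.02 ± 1.14 CPM (-1.91), Lrrn4 (-1.13), Wt1 (-0.88) and Krt18 (-0.86). That list had camera adjusted p = 8.61e-05, and adjusted p = 0.112 with an estimated correlation. Of 18 adventitial fibroblast genes, 10 fell and 3 rose, with Ly6c1 at -2.63, Scara5 at -1.82 and Gsn at 0.60 (camera adjusted p = 0.0516). The adventitial list passed under 12 of 25 alternatives, among them upper quartile scaling (adjusted p = 0.0365), total count scaling (adjusted p = 0.0205) and no expression filter (adjusted p = 0.0029). Of 9 pericyte genes, 5 fell and 3 rose, with Abcc9 at -2.67, Cspg4 at -1.30 and Notch3 at 0.93 (camera adjusted p = 0.133, and 0.027 with the filter of 1 CPM). Of 7 adipocyte genes, 3 fell and 1 rose, with Cd36 at -2.10, Fabp4 at -1.47 and Lpl at -1.85 (camera adjusted p = 0.133). Without knockdown replicate 4 the adipocyte list reached adjusted p = 0.0102 and the endothelial list adjusted p = 0.0498, and without the expression filter they reached adjusted p = 0.0339 and 0.00899. They passed under 3 and 4 of 25 alternatives. Of 8 neural and Schwann cell genes, 4 fell and none rose, with Ncam1 at -0.76, Prx at -0.72 and Tubb3 at -0.37 (camera adjusted p = 0.289). Of 8 macrophage genes, 3 fell and 2 rose, with Mpeg1 at -0.90, Cd74 at 1.64 and Cd68 at 0.87 (camera adjusted p = 0.724). Neither of the 2 tested lymphocyte genes passed, with Lck at -0.22 and Trac at -0.08, and Trac was at 0.02 with total count scaling. Both X inactivation and Y-linked transcripts were present in each library. Xist fell from 3.28 ± 0.431 to 1.21 ± 0.555 CPM (-1.42), while the Y-linked genes Eif2s3y (0.49), Kdm5d (0.37) and Uty (0.32) rose.

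**Figure D3:**
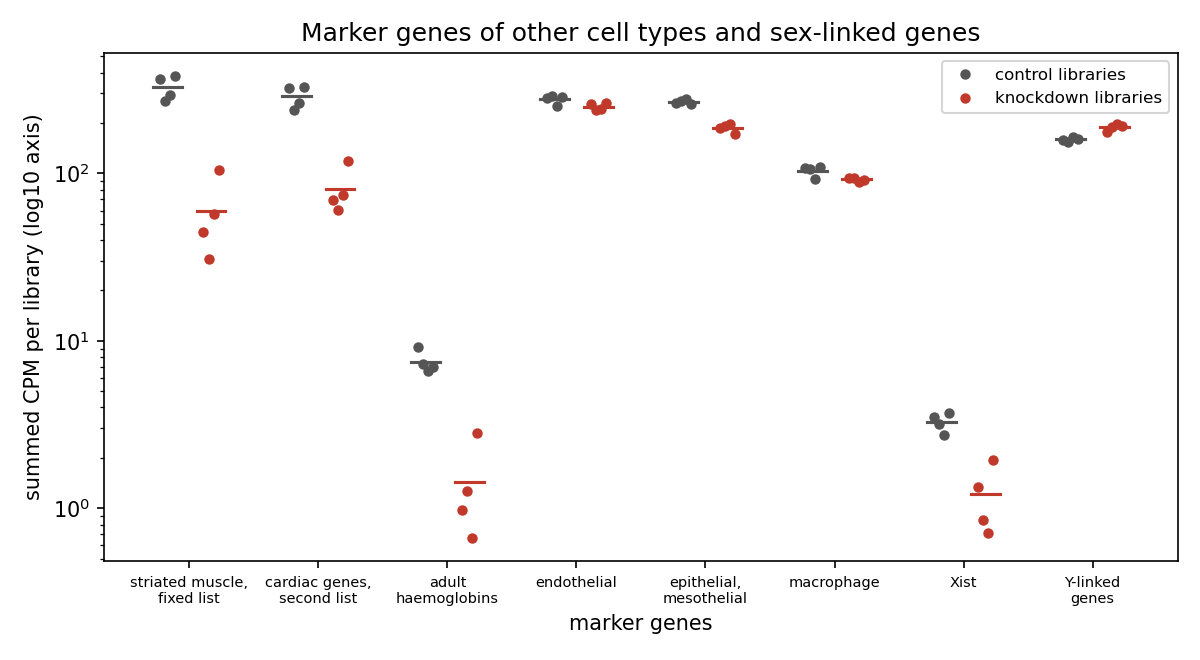
Summed CPM per library of marker genes (log10 axis), 4 control libraries in grey and 4 knockdown libraries in red, with the group mean as a bar. Striated muscle genes of the fixed list averaged 328 CPM in controls and 59.4 CPM in knockdowns, and adult haemoglobins 7.51 and 1.43 CPM.

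In all, 22 of 36 lists passed the camera test with its preset correlation of 0.01, 7 higher and 15 lower. Only the YAP and TGF-beta lists passed with an estimated correlation. Of 35 ways to part the 8 libraries 4 against 4, 4 gave at least 22 lists by the preset correlation, so the number of lists was within what other groupings gave. By fry, 33 lists moved on balance one way and 36 held genes that changed in either direction, a test that does not compare a list with other genes. The median and mean log2 fold changes were negative where the camera direction was up for oxidative phosphorylation, mitochondrial-encoded and pericyte genes.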

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

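A library was singled out where its gap to the nearest of the other 3 in its group was a large part of the group's range, a rule fixed before the data were examined. Of 388 groups of 4 tested this way, 18 (4.64%) were singled out, and chance gives about 1 in 20, or 5%. The share of counts on genes with Gm or Rik symbols was 1.48% in knockdown replicate 1 and 1.51% to 1.52% in the other knockdowns. In the knockdown group, Atf4 was 357 CPM in replicate 3 (369 to 370 in the others) and Cxcl10 was 9.63 CPM in replicate 3 (6.24 to 6.71). Fn1 was 916 CPM in replicate 2 (1003 to 1019 in the others), Klf12 6.92 CPM (7.89 to 8.08), Moxd1 0.582 CPM (0.862 to 0.868) and mt-Cytb 3510.5 CPM (3319 to 3326). Ifit3b was 125 CPM in replicate 4 (154 to 159 in the others), Lpl 4.55 CPM (1.27 to 1.79), Mcm5 53.9 CPM (65.5 to 67.0) and Tnnc1 6.26 CPM (4.24 to 4.52). Myocd was 0.136 CPM in replicate 1 (0.0388 to 0.0511 in the others). In the control group, Bmp4 was 106 CPM in replicate 3 (111 in each of the others), Sox5 23.5 CPM (28.2 to 28.6) and Tnc 57.1 CPM (67.2 to 69.2). Calr was 1326 CPM in control replicate 2 (1184 to 1207 in the others) and Eln was 100.3 CPM in control replicate 4 (96.1 to 96.8). In each gene named here all 4 knockdown values lay on the same side of all 4 controls.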

How the results depend on the processing

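Halved counts and GC and length offsets were chosen after the data were seen, and the other alternatives before. The number of genes past the threshold lay between 6332 (adjusted p under 0.01) and 8971 (total count scaling), against 8311, and between 7180 and 8032 with libraries left out. Of 8971 calls with total count scaling, 7150 were shared with the 8311. Over 2 fold, 798 genes passed with a filter of 1 CPM in 4 libraries, which tests fewer genes (12975), against 1453. The Sox6 log2 fold change missed the threshold at -2.13 (no filter, edgeR adjusted p = 0.0774) and -2.24 (DESeq2, adjusted p = 0.0704). It ranged from -3.22 to -1.76 with libraries left out, and the exact permutation p rose to 0.0571 without control replicate 2, knockdown replicate 3 or knockdown replicate 4, where 4 against 3 can give 0.0286. With 3 against 3 the p cannot be under 0.1. With an estimated correlation, which allows for genes that move together, 2 lists passed against 22. The lists of the synthetic state (median -0.43, adjusted p = 0.0572), contractile state (-0.38, adjusted p = 0.114), lysosome (0.29, adjusted p = 0.305) and core autophagy (0.16, adjusted p = 0.305) then missed it. By fry, 36 lists passed in either direction. With total count scaling or without the expression filter 27 lists passed, and under the other camera settings with the preset correlation 21 to 25. Of the 14 lists that did not pass, 8 passed under at least 1 camera alternative. Sign changes of log2 fold changes and of camera directions fell on genes and lists that did not pass. The median of the collagen list, which passed, turned from -0.077 to 0.024 with total count scaling, still lower by camera (adjusted p = 0.00372). Becn1 was -0.00022 with DESeq2 size factors, -0.0039 with DESeq2 and -0.039 to 0.051 with libraries left out. Trac was 0.021 with total count scaling, 0.13 with limma-voom, 0.076 with sample weights and -0.41 to 0.23 with libraries left out. Cnn1 was -0.55 to 0.10 with libraries left out. For oxidative phosphorylation the camera direction turned, with medians of -0.032 (no filter), -0.036 (DESeq2), -0.029 (limma-voom), -0.027 (sample weights), -0.078 (GC and length offsets), -0.028 (fry) and -0.049 to 0.0063 (libraries left out). It turned for pericyte genes with limma-voom (median -0.83) and with sample weights (-0.83), for macrophage genes with sample weights (0.018), and for mitochondrial-encoded genes with GC and length offsets (-0.25). The causes of these sign changes were not tested. Among named genes, 4203 of the values under all alternatives kept direction and call, 37 lost the call, 5 gained it and 18 changed sign. The replicate numbers gave no sign of pairing. With each group's mean taken out of log2 CPM, same-numbered libraries correlated at -0.031 to 0.057, and 3 of 8 correlated best with their own number. With the number as a replicate block 7985 genes passed, 7873 of them shared, with 1439 over 2 fold and 22 lists. At this depth Sox6 rests on 32 counts, which limits its ratio.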

Other observations

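Heart muscle transcripts beyond the fixed lists were also lower in the knockdown libraries. A second list of 40 cardiac genes, none of them in a fixed list, was written after the fixed list was read but before the levels of its own genes were read. Of its 32 tested genes with at least 1 CPM in controls, 28 fell and 1 rose, with a median log2 fold change of -2.22 and quartiles of -2.33 and -1.64. Ttn fell from 26.7 to 4.18 CPM (-2.67), Fabp3 from 26.3 to 5.34 CPM (-2.29) and Mb from 21.4 to 5.19 CPM (-2.04). Gata4 rose (0.16), while Txlnb (0.04) and Cmya5 (0.16) did not pass. Summed CPM of the second list were 69.2, 60.4, 74.6 and 119 in knockdown replicates 1 to 4, and those of the fixed list 44.6, 30.8, 57.2 and 105, so replicate 4 was highest in both. Among the knockdowns, adult haemoglobins, Xist and the endothelial sum were also highest in replicate 4. The epithelial and mesothelial, macrophage and Y-linked sums were not. The genes of the second list named here are outside the naming rule and were named after their values were seen.

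The rules for reading the tests on other scalings, batches, exon overlaps and splits with an estimated correlation were written after their results were seen. The other rules were written before. The other scalings themselves were fixed before the data were examined, whereas the GC and length offsets were added after the data were seen. For the fall of striated muscle transcripts, a candidate explanation is less RNA from heart muscle cells in the knockdown cultures, which would lower all their transcripts by 1 factor. Of the second list, 0% fell further than the median of the fixed list (-2.59) by more than 0.5 log2 and 2 SE, and 87.5% were called lower, which met the rule set for that explanation. The rule does not count genes that fell less, such as Ldb3 (-0.92 ± 0.09 SE) and Myl4 (-1.24 ± 0.18 SE). It therefore cannot show that all fell by 1 factor. Among the most abundant genes Myh6 fell from 162 to 28.0 CPM and Actc1 from 51.7 to 6.00 CPM, and no sort or gate is named in the labels. That rule was not set for the fixed list itself, where Myh7 fell by 5.0 on the log2 scale, more than the rest. Prox1 of the same list, singled out after its values were seen, fell by 4.45 ± 0.57 SE, on 93 and 4 counts. Separate changes of Myh7 and Prox1 are therefore open. Which cardiac genes VSMCs themselves express was not tested, and regulation by Sox6 remains an untested alternative.

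In all, 8311 genes changed although Sox6 lay near the detection limit. Of the 35 splits of the 8 libraries, 1, the real one, gave as many genes (8311, highest other 0 by edgeR, with 89 to 1347 at an unadjusted p under 0.05 against 9211), and likewise 1 for genes over 2 fold (1453, highest other 0). This is the smallest share that 35 splits can give. The other splits mix both groups, which widens the spread within each side and lowers their calls. The splits therefore show that the real grouping stands apart, but they cannot exclude chance. The number of genes did not rest on the choice of scaling, with a lowest count of 8324 over 3 other scalings. The directions did in part, since total counts gave 5926 higher and 3045 lower. GC content or transcript length as the source of the number is argued against by 8557 genes with offsets for both. A culture, animal or library batch that coincides with the groups cannot be told apart from the knockdown, because the labels give no batch. Xist (3.28 CPM in controls and 1.21 CPM in knockdowns) and adult haemoglobins (7.51 and 1.43 CPM) also differed between the groups. The endothelial and macrophage sums differed less clearly (exact permutation p = 0.0857 each). These values cannot tell cultures of different make-up from the knockdown. With group means taken out, same-numbered libraries correlated at only 0.015 on average, so the numbers gave no sign of a batch shared across the groups. The knockdown itself is the biological explanation that the design names. The labels name no other knockdown reagent and no rescue of Sox6. Loss of Sox6 can therefore not be told apart from other effects of the knockdown treatment. The size of the knockdown at the protein level was not analysed here.

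For gene lists by the preset correlation, 4 of the 35 splits gave as many lists (22, highest other 25), so chance cannot be excluded for their number. The 16 other splits with 3 control libraries on one side gave 15 to 25 lists, and the 18 with 2 on each side gave 0 to 7, so the high counts came from splits that keep most of the real grouping. With an estimated correlation 1 of the 35 splits, the real one, gave as many (2, highest other 0), and the median log2 fold change was largest in the real split for 26 of 36 lists.

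Tagln, Cnn1 and Myh11, abundant in most VSMCs, averaged under 10 CPM in both groups beside Acta2 at 1240 CPM in controls. Reads lost to overlapping genes are argued against for Cnn1 and Myh11, whose exons share 0% of their length with other genes. For Tagln, 67.9% of the exon length is shared and 639 bp are not. If reads fell evenly over its exons, such a loss would be 3.11-fold and leave Tagln low (0.339 and 0.678 CPM after scaling up), but the spread of reads along the gene was not analysed here, so the share of this loss is open. No biological explanation was tested, since low levels in both groups are not a contrast of the design.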
